A study of Pseudomonas putida KT2440 with 4 samples.

How the data were processed

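Strand-specific paired-end RNA sequencing had been carried out, per the series' design text, on wild-type Pseudomonas putida KT2440, a soil bacterium widely used to study the breakdown of small organic molecules. Cultures grew in minimal medium with 35 mM (S)-1,3-BDO or 35 mM (S)-3-HB as the only carbon source, at 30 °C and 200 rpm, to mid-exponential phase. RNA was stabilised, extracted with a column kit that removes genomic DNA, and made into libraries with a KAPA kit, per the labels' protocols. There were 4 libraries, 2 for each carbon source, which the design text describes as biological duplicate cultures. Replicate 1 and 2 are the numbers in the sample titles.

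The authors deposited 1 table of TPM (transcripts per 1000000, which scales each gene's reads by its length and each library to a fixed total), with 1 column per library. The submitters' processing notes name Bowtie 1.0.0, featureCounts and DESeq2. The genome build, annotation, gene lengths and counting options are not given in the sources used here. The 5630 rows carry identifiers without gene names. In the file, both (S)-1,3-BDO columns summed to 1000000 TPM, while the (S)-3-HB columns summed to 977772 and 980921 TPM. This left 2.22% and 1.91% of those libraries outside the rows with values. In 1 row the (S)-3-HB cells held a text in place of a value. That row was left out, and 5629 rows were used. Whether the missing TPM belonged to that row or to rows not listed cannot be told from the values. The 2 pairs of columns therefore differed in how complete they were, and this difference coincides with the carbon source. Whether the 4 libraries were sequenced in the same run is not stated in the sources used here, so a difference between runs, if there was one, would be part of every difference between the carbon sources.

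The files do not pair the identifiers with names or coordinates. None of the 5630 identifiers was found in the reference gene table used here, which covers another assembly of the strain with its own identifiers (0 matched). The 36 gene lists and the 14 single genes fixed before the data were examined were written with older locus tags or gene symbols, and 0 of their 634 locus tags occurred in the table, so no list was tested, and no gene is named by function. Only 2 identifiers that rose and 2 that fell are printed. They are the largest changes in each direction among genes with adjusted p under 0.05 whose libraries did not overlap between groups, the part of the naming rule that could be applied. Its other parts (the 10 largest changes each way, the 5 most abundant genes each way with at least a 2-fold change, and the 3 longest runs each way) are given as groups.

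Because TPM values are not counts, differences were tested with limma 3.58.1 (R 4.3.3; lmFit and eBayes with a trend in the variance) on log2(TPM + 1), (S)-1,3-BDO minus (S)-3-HB, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 4 libraries entered the fit with the carbon source as the only term. Genes with a mean of at least 5 TPM over the 4 libraries were tested (4883 genes; 746 were not). Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so every adjusted p rests on limma's moderated variance, with 2 residual and 7.13 prior degrees of freedom. Runs were stretches of at least 4 rows listed one after the other that all passed the threshold in the same direction, with a row that was not tested ending a run; their chance level came from 1000 permutations of the calls over the tested genes, and from 200 for each alternative. The row order of the table is the order of its identifiers and is not a set of coordinates.

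Depth is not stated with TPM, but the low values moved in steps. With c reads, a gene's TPM is c times a step set by the library and the gene length, and the steps of the 4 columns relative to each other could be found from genes under 3 TPM. With these steps, 99.8% of the 5629 genes had a set of 4 whole numbers in the ratio of their TPM values (tolerance 0.002 of a read plus rounding error); the exceptions above 0 in at least 2 libraries were the 2 most abundant entries. Among 3302 genes under 50 TPM, 97.8% had such a set at no more than 1000 reads in the lowest library, against 0.727% when the steps of 2 columns were deliberately set wrong. The smallest such set was taken as the reads of a gene, so each total is a minimum. In data simulated from these libraries, 92.4% of 5619 genes came back exactly and 99.9% exactly or divided by a whole factor. The recovered reads came to at least 10654293 and 11330091 for (S)-1,3-BDO and 11273142 and 11906318 for (S)-3-HB, leaving out the 2 most abundant entries. Reads are not independent molecules, so they bear on counting error only.

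The limma fit was tested on simulated data with the libraries' own depth (5619 genes, 200 changed). Every simulated gene had the same spread, a coefficient of variation of 0.0929, the median between duplicates among genes with more reads. The fit called 97.9% of the tested 2-fold changes and 100% of the 4-fold changes in the right direction, and 1.05% of its calls were false. In the data the spread differs between genes, neighbouring genes vary together and far more genes were called. These rates therefore need not hold there. Replicate numbers were checked as pairs: over the tested genes, the difference between replicates 1 and 2 on (S)-1,3-BDO had a correlation of -0.14 with that on (S)-3-HB, across genes, so the numbers were not treated as pairs. Duplicates were not copies of one library: their recovered reads differed by 23.9 and 32.8 times the sampling variance per gene. Alternatives fixed before the data were examined covered the pseudocount, the filter, 3 rescalings, the variance model, a replicate block and leaving out each library. Added after seeing the data were a crossed block, rescaling over the listed genes, leaving out the 5 most abundant entries, and limma's voom on the recovered reads with and without rescaling. Rescaling over protein-coding genes alone, and the alternatives of the gene list tests, were not run, because the identifiers have no gene type or name here.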

Results

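The transcriptome of wild-type P. putida KT2440 was measured in 2 cultures grown on (S)-1,3-BDO and 2 grown on (S)-3-HB, to follow the route by which the strain degrades (S)-1,3-BDO. The table listed 5630 genes by identifier, without names, and transcript levels are given as deposited TPM. Median levels were 31.8 and 30.9 TPM in the (S)-1,3-BDO libraries and 31.9 and 34.6 TPM in the (S)-3-HB libraries. At least 10654293 and 11330091 reads lay behind the (S)-1,3-BDO columns and 11273142 and 11906318 behind the (S)-3-HB columns, with a median of 380 to 469 reads per gene. Between 15 and 18 of the genes in each library were listed at 0.

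Duplicates resembled each other more than libraries from different carbon sources did. Across 5629 genes, Pearson's r of log2(TPM + 1) was 0.991 between the (S)-1,3-BDO duplicates and 0.989 between the (S)-3-HB duplicates (genes are not independent replicates). It lay between 0.921 and 0.923 for the 4 pairs across carbon sources. The SD of the log2 difference was 0.305 and 0.329 within the groups and 0.882 to 0.900 between them. One library stood apart in its most abundant entries: the leading 2 entries took 24.1% and 25.5% of TPM on (S)-1,3-BDO and 22.4% in (S)-3-HB replicate 1, but 12.1% in (S)-3-HB replicate 2.

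The comparison of the carbon sources asked which transcripts accompany growth on (S)-1,3-BDO rather than on (S)-3-HB. Few genes went from near silence to a high level: 3 called genes lay under 10 TPM on (S)-3-HB and over 1000 TPM on (S)-1,3-BDO, and 0 the other way round. With over 100 TPM in place of over 1000, the count was 5 in each direction. PP_RS13925 rose from 5.29 ± 0.28 TPM on (S)-3-HB to 14069 ± 24 TPM on (S)-1,3-BDO (SD, n = 2 each), where it ranked as number 4 of all entries in both libraries. PP_RS13865 rose from 1.98 ± 0.12 to 10122 ± 683 TPM (SD, n = 2 each). Their log2 fold changes were 11.13 ± 0.15 and 11.73 ± 0.15 (SE), each with an adjusted p of 1.15e-10 in limma; with a pseudocount of 5 in place of 1 they were 10.42 and 10.50, and the second reached 12.58 after quantile normalization. At least 189 and 185 reads of PP_RS13925 stood behind its (S)-3-HB values, against at least 432884 and 482087 on (S)-1,3-BDO, while PP_RS13865 had at least 24 and 20 reads on (S)-3-HB. The files give neither gene a name, position or function.

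The largest falls were smaller. PP_RS19335 fell from 841 ± 536 TPM on (S)-3-HB to 5.79 ± 0.17 TPM on (S)-1,3-BDO (SD, n = 2 each), a log2 fold change of -6.79 ± 0.36 (SE; limma adjusted p = 1.84e-06). Its (S)-3-HB duplicates lay at 461.9 and 1220 TPM, and the log2 fold change was -7.49 without replicate 1 and -6.09 without replicate 2, so the size of this fall is less certain than its direction. PP_RS19675 fell from 799 ± 145 to 9.17 ± 5.40 TPM (SD, n = 2 each), a log2 fold change of -6.40 ± 0.32 (SE; limma adjusted p = 1.41e-06). The 10 genes with the largest rises spanned log2 fold changes of 5.53 to 11.73, and the 10 with the largest falls -6.79 to -3.85.

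**Figure D1:**
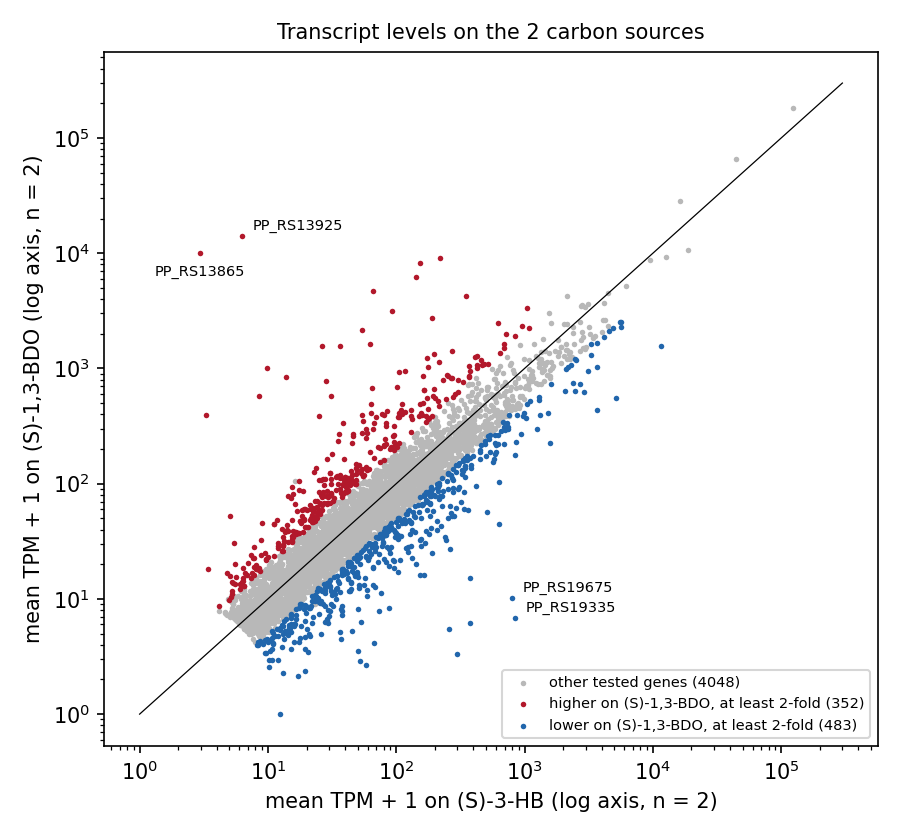
Mean TPM + 1 of each tested gene on (S)-3-HB (x axis, log scale) against (S)-1,3-BDO (y axis, log scale), n = 2 libraries each; red and blue points passed adjusted p under 0.05 with at least a 2-fold change, and the line marks equal levels. PP_RS13925 and PP_RS13865 stand apart at the upper left, at 14069 and 10122 TPM on (S)-1,3-BDO and 5.29 and 1.98 TPM on (S)-3-HB.

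Of 4883 genes tested, 2278 differed at an adjusted p under 0.05 (limma), 850 higher and 1428 lower on (S)-1,3-BDO. With a change of at least 2-fold, 352 genes were higher and 483 lower, but 458 higher and 341 lower after median-of-ratios rescaling. At least 8-fold, the numbers were nearly even, with 25 genes higher and 24 lower, and at 32-fold or more 14 were higher and 5 lower. The excess of lower genes depended on the scaling: 37.3% of the called genes were higher in the TPM as deposited, against 50.9% after median-of-ratios rescaling and 51.2% after trimmed mean rescaling. The median gene lay 0.16 below 0 on the log2 scale as deposited and at 0.00 after either rescaling, so called changes near that shift have no certain direction. The shift also depended on the libraries. As deposited, the median was -0.24 without (S)-3-HB replicate 1 and -0.09 without (S)-3-HB replicate 2. Without (S)-1,3-BDO replicate 1 or 2 the median was -0.18 or -0.13. All 49 genes changed 8-fold or more stayed past the threshold in the same direction under the 19 alternatives run, except that 46 of them were tested with a minimum of 20 TPM.

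The risen genes made up a large part of the transcript pool. The 352 genes higher by at least 2-fold held 16.4% ± 0.27 of the listed TPM on (S)-1,3-BDO and 3.20% ± 0.16 on (S)-3-HB (SD, n = 2 each). The 25 that rose at least 8-fold held 7.71% ± 0.17 against 0.186% ± 0.018. In the other direction, the 483 genes lower by at least 2-fold held 5.97% ± 0.08 on (S)-1,3-BDO and 17.7% ± 1.67 on (S)-3-HB, and the 24 that fell at least 8-fold held 0.122% ± 0.017 against 1.43% ± 0.29. These sets were chosen on the same libraries, so their shares describe size and are not a further test. The strongest rises were in abundant genes and the strongest falls in rarer ones: on the carbon source where they were higher, the median level was 1555 TPM for the 25 risen genes and 158.6 TPM for the 24 fallen genes. Of the 25, 14 lay in 1 run of 22 neighbouring genes, and of the 24, 6 lay in 1 run of 16. The genes behind these medians are therefore not independent cases. The 5 most abundant genes among those higher by at least 2-fold reached 6247 to 14069 TPM on (S)-1,3-BDO. The 5 most abundant among those lower by at least 2-fold lay at 4873 to 11670 TPM on (S)-3-HB and still at 1561 to 2522 TPM on (S)-1,3-BDO, with log2 fold changes of -2.91 to -1.10. Of the 100 most abundant entries on each carbon source, 66 were shared; 27 of the (S)-1,3-BDO list were higher there by at least 2-fold, and 27 of the (S)-3-HB list were lower on (S)-1,3-BDO by at least 2-fold.

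The changed genes lay close together in the table. Stretches of at least 4 consecutively listed genes called in one direction numbered 109 (40 higher, 69 lower) and held 599 genes, against a median of 24 and a highest value of 40 in 1000 permutations of the calls (permutation p = 0.001, the smallest they can give). The number of runs depended on the libraries: it was 65 without (S)-1,3-BDO replicate 1, 61 without (S)-1,3-BDO replicate 2 and 68 without (S)-3-HB replicate 2, where the calls permuted 200 times each reached at most 18, 14 and 16. The higher runs numbered 24 without (S)-3-HB replicate 1. The excess of lower runs depended on the scaling: after median-of-ratios rescaling 53 runs were higher and 43 lower. The permutations treat genes as independent, while the differences between duplicates were also alike in neighbouring genes (Spearman's rho across genes 0.215 on (S)-1,3-BDO and 0.296 on (S)-3-HB).

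The longest run held 22 consecutively listed genes, all higher on (S)-1,3-BDO, with PP_RS13865 as its first member and PP_RS13925 at place 13. Together they rose from 2233 ± 404 TPM on (S)-3-HB to 64078 ± 2418 TPM on (S)-1,3-BDO (SD, n = 2 each), or from 0.228% ± 0.042 to 6.41% ± 0.24 of the listed TPM. All 22 rose at least 2-fold, 18 at least 4-fold and 14 at least 8-fold, with a largest adjusted p of 0.000339 (limma), and 11 of them exceeded 1000 TPM on (S)-1,3-BDO whereas none did on (S)-3-HB. The rise was uneven along the run. It was smallest at place 4, with a log2 fold change of 1.57 ± 0.18 (SE), and beside PP_RS13925 the genes at places 14, 15 and 16 reached 9128, 6247 and 3147 TPM from 217, 141 and 91.9 TPM. All 22 members were called in the same direction under every alternative run.

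Other long runs rose less in total. A run of 12 genes rose from 1224 ± 127 to 6066 ± 142 TPM (SD, n = 2 each; median log2 fold change 2.40), and all 12 were called under every alternative run. The third place was shared by 3 runs of 9 genes. One rose from 745 ± 98.4 to 6692 ± 543 TPM; its 5 central genes went from 83.9 ± 48.7 to 4929 ± 531 TPM together, with log2 fold changes of 5.53 to 6.90. The median log2 fold change of these 9 was 5.53, and it was 4.92 without (S)-3-HB replicate 1 and 6.14 without (S)-3-HB replicate 2; at fewest 8 of the 9 were called over the alternatives. The other 2 rose from 726 ± 2.51 to 3018 ± 289 TPM (median log2 fold change 2.29) and from 2411 ± 231 to 4986 ± 1306 TPM (1.36). Of the 10 genes with the largest rises, 4 lay in the run of 22 and 5 in the run of 9 with the median of 5.53.

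**Figure D2:**
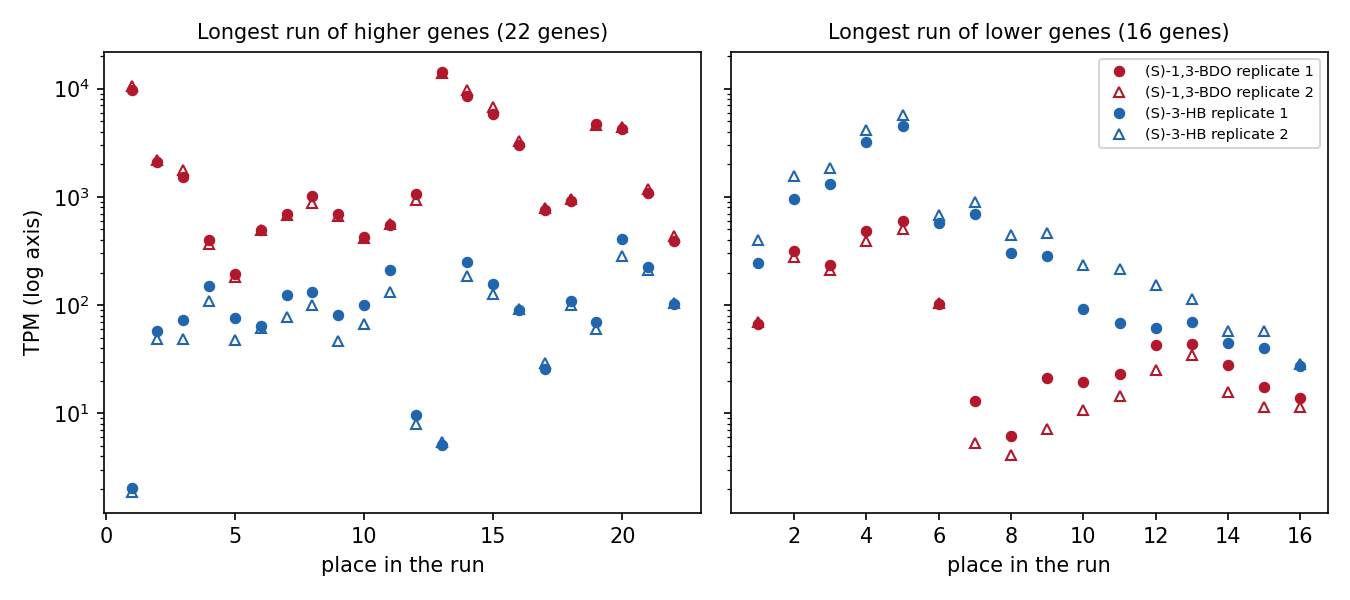
TPM (y axis, log scale) of each gene in the longest run of higher genes (left, 22 genes) and of lower genes (right, 16 genes), by place in the run; each point is one library. The (S)-1,3-BDO libraries lie above the (S)-3-HB libraries at every place on the left and below them at every place on the right.

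The longest run of lower genes held 16 members, PP_RS19675 among them at place 7. Together they fell from 14751 ± 3165 TPM on (S)-3-HB to 1864 ± 228 TPM on (S)-1,3-BDO (SD, n = 2 each), or from 1.51% ± 0.32 to 0.186% ± 0.023 of the listed TPM. All 16 fell at least 2-fold, 11 at least 4-fold and 6 at least 8-fold, with a largest adjusted p of 0.00967 (limma). The fall was steepest at places 7, 8 and 9, with log2 fold changes of -6.40, -5.92 and -4.77, while the most abundant members, at places 4 and 5, went from 3669 and 5124 TPM to 438 and 550 TPM. Between 14 and 16 of the members were called over the alternatives. PP_RS19335 stood in another run, of 8 genes, in which 3 genes side by side fell from 1394 ± 898 to 12.6 ± 1.97 TPM together (SD, n = 2 each). The next longest lower runs changed less: one of 15 genes fell from 797 ± 77.2 to 409.7 ± 1.34 TPM in total, and one of 10 genes from 1445 ± 104 to 831 ± 89.7 TPM (SD, n = 2 each). At fewest 11 of the 15 and 8 of the 10 were called over the alternatives.

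**Figure D3:**
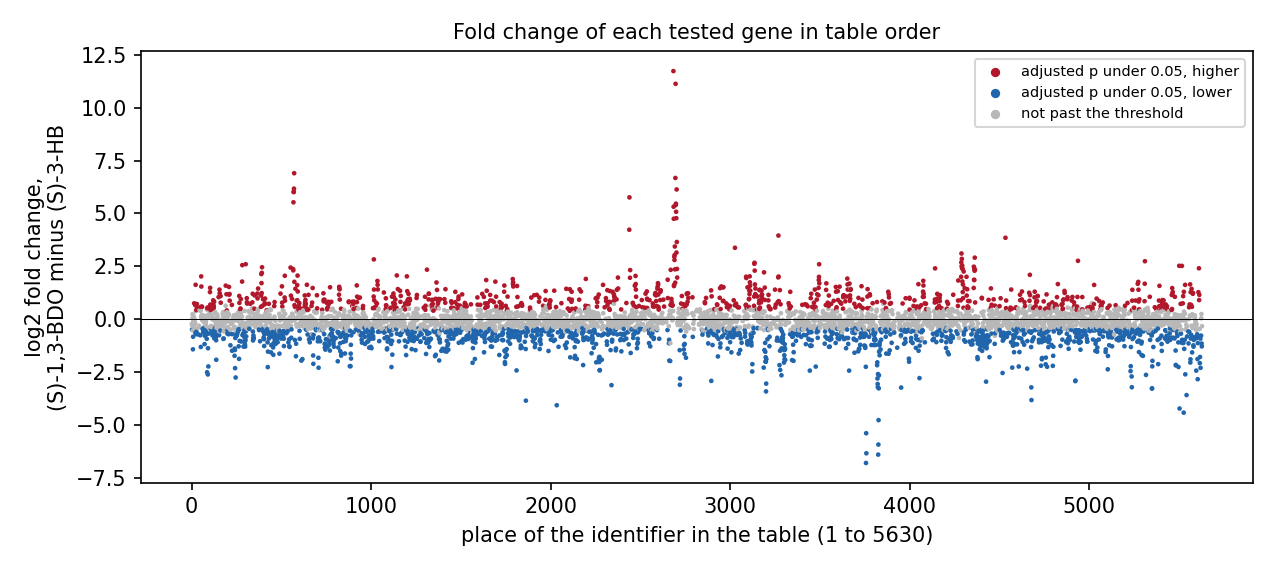
Log2 fold change of each tested gene, (S)-1,3-BDO minus (S)-3-HB (y axis), by the place of its identifier in the table (x axis); red and blue points passed adjusted p under 0.05. The tallest column of red points is the run of 22 genes, whose largest log2 fold change was 11.73, and the lowest blue points reach -6.79.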

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

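The count of 2278 called genes stayed between 1621 and 2286 under the alternatives fixed before the data were examined and between 2215 and 2698 under those added afterwards, all within 1.5 times of the value as designed, as were the counts of higher and lower genes with and without a 2-fold minimum. The split between higher and lower genes moved with the scaling, from 37.3% higher to 50.9%, 51.2% and 47.7% under the 3 rescalings (median of ratios, trimmed mean, quantile), and voom on the recovered whole reads gave 34.0% without and 52.4% with trimmed mean rescaling. Of the 2278 genes, 1924, 1915 and 2011 were called in the same direction under the 3 rescalings, 2269 with a 0.1 pseudocount, 2214 of the 2539 of voom, 1906 in voom with trimmed mean rescaling, and 1577 to 1815 without a library. Leaving out a library gave 1621 to 1986 called genes, where the lone library left in a group is assumed to vary like the other group. The log2 fold changes of PP_RS13865, PP_RS13925, PP_RS19335 and PP_RS19675 kept their direction and stayed past the threshold under each alternative, but the sizes of 3 moved by more than 1.5 times: to 10.50 and 10.42 for the first 2 and -6.13 for PP_RS19335 with a pseudocount of 5, to 12.58 for PP_RS13865 after quantile normalization and 12.46 in voom with rescaling, and to -7.49 and -6.09 for PP_RS19335 without an (S)-3-HB library. Block fits and fits without an (S)-1,3-BDO library rest on at least 25.02 prior degrees of freedom, against 7.13 as designed.

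The number of runs ranged from 61 to 93 over the fits that left out a library, the higher runs from 22 to 28 and the lower runs from 37 to 69. The lower runs numbered 43 after median-of-ratios or trimmed mean rescaling, 104 in voom on the recovered reads and 45 in voom with trimmed mean rescaling. Pearson's r with a pseudocount of 5 was 0.992 for the lower of the within-group pairs and 0.919 for the highest pair across groups. For all of these the cause was not tested. The fits without a library also called fewer genes, and whether this lowered the number of runs was not tested. With a replicate block 2195 genes were called; the numbers mark no stated pairing, and crossing the (S)-3-HB numbers, tried after seeing the data, called 2698. By recovered reads over the 4 libraries, 24 of 41 tested genes were called under 100 reads, 231 of 599 from 100 to 500, 656 of 1567 from 500 to 2000 and 1367 of 2674 from 2000 on (median SE 0.246, 0.210, 0.181 and 0.163); past the first class the share rose with reads. Genes under 5 TPM on average were tested only in the fit without a filter, which called 2282.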

Other observations

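The tests on the split of calls, on groups of strongly changed genes, on the TPM missing from the (S)-3-HB columns and the control with wrong gene lengths, which narrowed the planned test of lengths, were chosen only after the result was seen.

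Strongly changed genes lay near each other in the table more often than chance gave. Of the 25 genes that rose at least 8-fold, 21 lay within 3 places of another such gene, in 4 groups, and of the 24 that fell, 15 did so in 5 groups. Random draws of as many tested genes gave a median of 0 and at most 6 and 8 (permutation p = 0.001 for each, the smallest that 1000 draws can give). Outside the runs described above, a pair of neighbouring genes rose from 182 ± 22.9 to 8868 ± 58.1 TPM together (SD, n = 2 each), with log2 fold changes of 4.23 and 5.76.

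More genes were called lower than higher on (S)-1,3-BDO, and a candidate explanation is the weight of a few very abundant entries, which lowers every other TPM in a library. With the 5 most abundant entries left out and the columns rescaled, 46.9% of the called genes were higher, against 37.3% as deposited, and the median difference between the (S)-3-HB duplicates went from -0.14 to 0.04 on the log2 scale. Voom on the recovered reads, which lack the 2 most abundant entries, gave 34.0% higher and a median log2 fold change of -0.21. That fit scales by recovered reads in place of TPM and was not run with these 2 entries. It therefore cannot show what leaving them out does. In the TPM scaling, the median log2 fold change was -0.16 as deposited and -0.05 without the 5 most abundant entries. The explanation stays open. The TPM missing from the (S)-3-HB columns acts the other way. Rescaling each column to 1000000 over the listed genes can only raise the (S)-3-HB values, and it left 35.0% of the called genes higher. As a matter of scale the missing TPM therefore does not account for the excess. That direction was fixed by the column sums, so the rescaling was not a test. What the abundant entries are is unknown here, and a real difference in total messenger RNA between the cultures was not tested.

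Genes listed next to each other changed together, as the genes of one transcription unit would (a hypothesis; the table gives no coordinates or strands). Over 4495 pairs of neighbours, Spearman's rho of the fold change was 0.396, across genes, and at most 0.047 in 1000 permutations. It was not carried by the strongest groups alone, since it stayed at 0.356 over the 4237 pairs left without genes changed 4-fold or more. Noise shared by neighbours stays open as part of it, since the difference between duplicates had a rho of up to 0.296. The 2 rho differed by a 95% bootstrap interval of 0.052 to 0.149, which lies above 0 but spans the margin of 0.1 set before. This difference does not measure how much of the 0.396 comes from noise. Differences between duplicates were the smaller part of the spread: the SD of the log2 difference was 0.305 and 0.329 within the groups and 0.882 to 0.900 between them.

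The (S)-3-HB columns lacked part of their TPM and the (S)-1,3-BDO columns did not. The 2 pairs may therefore have been made differently, which bears on the changes of 8-fold or more. A control asked whether whole-read sets would reveal lengths that differ between the columns: (S)-3-HB reads were changed by each gene's own fold change and divided by a length wrong by that factor. In it 31 of the 49 genes, 25 risen and 6 fallen, lost their set in at least 90% of 20 draws each. An earlier form, which moved the deposited values by a further 8 to 64 times, had given 46; the later form decides here because its values stay near those deposited. For the 31, different lengths are argued against, since 0% lacked a whole-read set with 1 length for all 4 columns. For the other 18, all fallen, they cannot be told apart from a change in level, because the control did not detect a wrong length reliably; PP_RS19335 and PP_RS19675 are among them. Lengths wrong by at most 2 times were detected as often in 47 of the 49, but such lengths are too close to give an 8-fold change. The TPM missing from the (S)-3-HB columns is argued against as the source of the 8-fold changes, since completing a column to 1000000 shifts a log2 fold change by at most 0.032. The counting options of the columns are not given in the sources used here and were not tested. The carbon source, which the design names, stays open as the explanation and was not tested apart from these.

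Faster growth raises the copy number of genes near the replication origin, so a difference in growth rate might leave a wave in the fold changes along the chromosome. In table order, with fold changes limited to 2 on the log2 scale either way, the first harmonic had an amplitude of 0.050, against a permuted median of 0.037 (permutation p = 0.275, blocks of 50 genes, 1000 permutations). The prediction that such a p would exclude the wave was too strong, because the bootstrap upper bound of the amplitude was 0.112 and the table order only stands in for position.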
